A study of Mus musculus with 8 samples.

How the data were processed

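RNA was measured in pancreatic epithelium of mouse embryos dissected at embryonic day 15.5, dorsal and ventral parts together. The Sox9 mutant group held 4 arrays from embryos homozygous for a loxP-flanked Sox9 allele and carrying Rosa26-CreER, a recombinase that tamoxifen activates. The wild-type group held 4 arrays from littermates that carried Rosa26-CreER without the floxed alleles. Dams received 6 mg of tamoxifen per 40 g at embryonic day 12.5. Each RNA sample pooled 4 pancreata, so the spread between arrays is a spread between pools of 4 embryos and not between single embryos. About 250 ng of RNA was labelled with Cy3 and hybridised to a one-colour Agilent array of design 014868.

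The deposited scanner files hold, per the file headers, the output of Agilent Feature Extraction 9.5.3.1. Their processed signal is an intensity in linear scanner units, from which the scanner software had subtracted background and removed spatial trends within the array, with low values replaced by a surrogate, and without normalization between arrays. The same deposited files give raw spot and local background brightness as an intensity without any normalization. The deposited series table also holds an intensity on a linear scale, for 40928 probes. The authors name limma as their tool and give neither its version nor their steps. The series table's values followed the raw median spot signal across probes with a Pearson r of at least 0.9996 on 7 arrays and of 0.9817 on the array of mutant replicate 2, and their median log2 values lay between 8.30 and 8.32 on those 7 arrays and at 8.47 on that array. Its values were not used for the reported results, only as an alternative.

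Control spots and spots the scanner software marked as outliers were left out, spots of one probe were averaged on the log2 scale, and the 75th percentile of each array was subtracted. All log2 levels below are therefore relative to the 75th percentile of the array. Of 41174 probes, 29447 were well above background, by the scanner software's own call, on at least 4 of the 8 arrays, counted without regard to genotype. For each gene the probe with the highest mean over all 8 arrays was kept, and a probe without a gene name counted as a feature of its own, which gave 19384 features. Of these, 15923 had a current gene symbol. Names came from the probe annotation in the files, matched to a RefSeq gene table of assembly GRCm38.p6 that was used for names only: 24375 probes matched through an accession, 6301 through their symbol, 2426 through a synonym, and 8072 had no current symbol. Probe coordinates are those of the files, on mouse assembly mm8 (NCBI36). Older symbols of the array are given with the current symbol beside them.

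One linear model with genotype as its only term was fitted to all features with limma 3.58.1 (lmFit and eBayes, two-sided moderated test) in R 4.3.3, with data.table (version 1.17.8) for reading the files, and p-values were adjusted by the Benjamini-Hochberg method. A feature was called at an adjusted p under 0.05. Values are given as the mean ± SD of the 4 pools of a genotype. Where a probe was not well above background on any array of one genotype, the fold is a lower bound, for which that genotype's levels were set to no less than the lowest level called well above background on each array. For Sox9 an exact two-sided permutation test of the difference of means was added, for which the smallest possible p with 4 against 4 arrays is 0.0286.

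For 26 gene lists, camera of the limma package tested whether a list's members changed more in one direction than other genes did (two-sided, preset correlation of 0.01 between genes, Benjamini-Hochberg over the 26 lists). The lists covered duct and trunk, endocrine progenitor, endocrine hormone and secretion, acinar enzyme, acinar transcription factor, early multipotent progenitor and pan-epithelial genes, the Notch, FGF, Wnt and Hedgehog pathways, YAP targets, primary cilium and cystic kidney genes, SOX9 cartilage targets, basement membrane and epithelial matrix, cell cycle, p53 targets, the unfolded protein response and immediate early genes. They also covered genes of mesenchyme, endothelium, erythroid cells, myeloid and lymphoid cells, neurons and Schwann cells, liver, gut and spleen, and Y-linked genes with Xist. Camera with a correlation estimated from the data, and fry, were run beside it. An exact two-sided permutation test of each list's mean over its members was added after the data were seen.

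The groups, the model, the lists and the rule for naming genes were fixed before the data were examined. The rule named Sox9, 20 key genes, the 6 genes with the largest rise and the 6 with the largest fall among called genes whose 4 mutant values all lay on one side of the 4 wild-type values and whose probe was well above background on all 4 arrays of at least 1 genotype, and up to 4 called members of each list, by adjusted p, or up to 2 members with the smallest p where a list had none. Unannotated transcripts were skipped. A few genes that the rule names are not reported here, though the counts of called genes include them.

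The alternatives tried were normexp background correction with an offset of 50, quantile normalization, centring on the median, no filter on dim probes, a filter that asks for all 8 arrays, all probes as features, the mean over a gene's probes, eBayes with trend and robust options, array weights, the replicate number, which is also the position on the slide, as a block, the submitters' series table, an added limit of 2-fold, and each array left out in turn. Quantile normalization of 7 arrays without mutant replicate 2, the lists without Sox9 itself, the other 2 Sox9 probes and the permutation test of list means were added after the data were seen, as was the median log2 fold change under both scalings without mutant replicate 2. A slide block was not run, because each slide held 1 genotype only.

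The steps were tested on simulated data for 19384 genes, with 50 changed genes for each fold. Noise was drawn independently for each gene, with its real within-genotype SD, the same on every array. In the real arrays the added spread sat on mutant replicate 2 and varied with signal level, and slide matched genotype. The shares and false calls below therefore describe the steps under simulated noise, and not the error rate in these data. With all 8 arrays, 34% of genes simulated at 1.5-fold, 56% at 2-fold, 84% at 4-fold and 92% at 8-fold were called, with 11 calls among unchanged genes and 0 changed genes called with the wrong sign. With the 7 arrays that leave out mutant replicate 2 the shares were 48%, 80%, 96% and 100%, with 16 calls among unchanged genes. Precision is limited by the number of arrays and by the spread that mutant replicate 2 adds. The median standard error of a log2 fold change was 0.12 with all 8 arrays and 0.088 without mutant replicate 2.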

Results

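Gene expression was profiled on one-colour arrays in pancreatic epithelium at e15.5, in 4 pools from embryos homozygous for floxed Sox9, 3 days after their dams received tamoxifen, and in 4 pools from wild-type littermates. Sox9 encodes a transcription factor of pancreatic progenitors and ducts, and the comparison asks which pathways depend on it during the secondary transition, the stage at which endocrine, acinar and duct cells form. The median processed signal of an array was between 219 and 272 scanner units on 7 arrays and 756 on the array of mutant replicate 2. On the 7 arrays, 69.6% to 74.0% of probes were well above background and the negative control probes had a median signal of 69.8 to 87.4 units. On the array of mutant replicate 2 these values were 86.1% and 282 units, and its median Pearson correlation with the other arrays of its genotype, across genes, which are not independent replicates, was 0.923 against 0.9935 to 0.9956 for the other 7. All wild-type pools were on slide 1 and scanned in run 1, and all mutant pools were on slide 2 and scanned in run 2, so slide and scan cannot be told apart from genotype and no within-slide value could be computed.

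**Figure D1:**
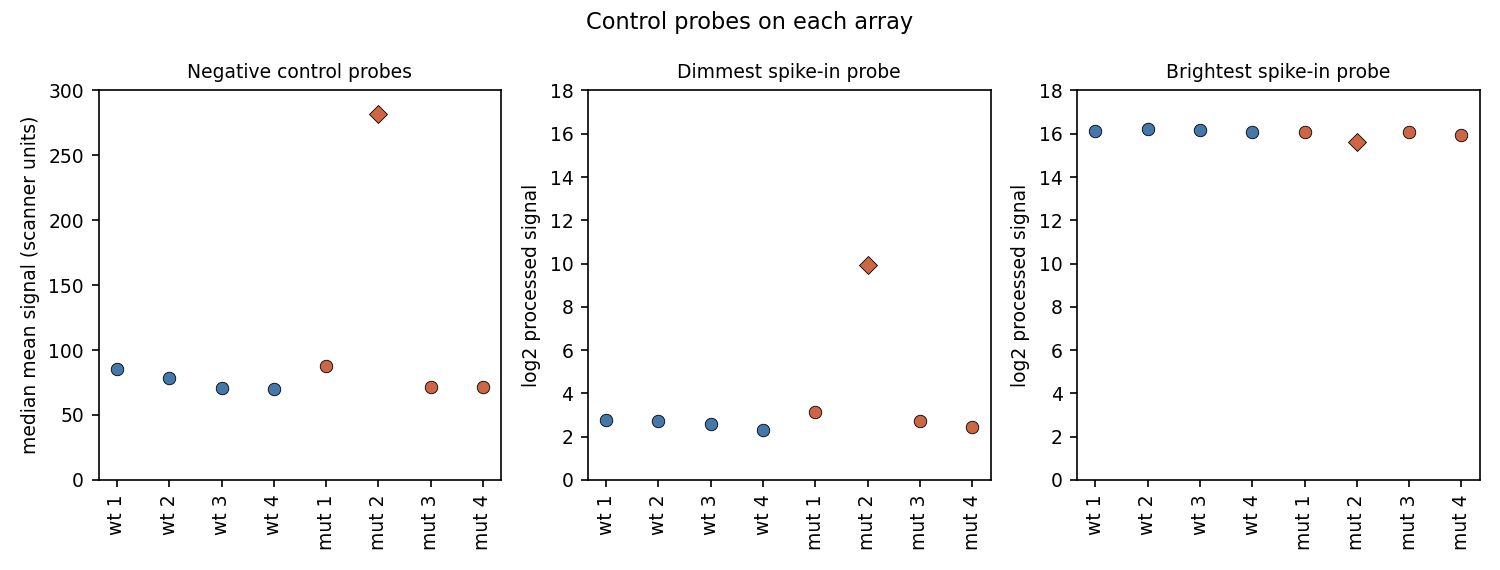
Signal of control probes on each array (wt, wild type; mut, Sox9 mutant; 1 point per array; a diamond marks mutant replicate 2): the median mean signal of the negative control probes in scanner units, and the log2 processed signal of the dimmest and the brightest spike-in probe. Negative controls read 282 units on the array of mutant replicate 2 and at most 87.4 on the other 7, and the dimmest spike-in read 9.94 there against at most 3.14.

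Of 19384 genes and unnamed transcripts tested, 431 were higher and 628 were lower in Sox9 mutant epithelium, and 135 of the higher and 137 of the lower changed at least 2-fold. The median absolute log2 fold change of the 1059 called genes was 0.67. At an unadjusted p under 0.05 there were 4887 genes. In 4952 genes, or 25.5%, the 4 mutant values all lay above or all below the 4 wild-type values, where chance gives 2.86%. Every left-out array changed the number of calls by more than 1.5 times. Without mutant replicate 2 there were 3357 calls, 1399 higher and 1958 lower, and these included all 1059 genes with the same direction. The number of calls was 359 without wild-type replicate 1, 386 without wild-type replicate 2, 371 without wild-type replicate 3 and 541 without wild-type replicate 4. It was 447 without mutant replicate 1, 488 without mutant replicate 3 and 484 without mutant replicate 4. The median log2 fold change over all genes was 0.01. Centring arrays on their median instead of their 75th percentile moved it to -0.38. Most of that shift came from mutant replicate 2, since without that array the median log2 fold change was -0.02 with the 75th percentile and -0.05 with the median. For 542 second probes of called genes, 72.3% had the direction of the gene's main probe, against 58.6% of 9521 second probes of uncalled genes.

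The main Sox9 probe (A_52_P214630, chromosome 11, 112603585 to 112603644) fell from a log2 level of 1.74 ± 0.07 in wild type to 0.42 ± 0.08 in mutants (SD, n = 4 pools each). The log2 fold change was -1.32 with an SE of 0.07 and an adjusted p of 8.14e-04 (limma), a 2.49-fold decrease that left 40.2% of the wild-type signal. All 4 mutant pools lay below all 4 wild-type pools (exact two-sided permutation p of 0.0286, the smallest possible). A second probe (A_52_P577484, chromosome 11, 112601784 to 112601843) was brighter in wild type, at 2.01 ± 0.12. It fell by 2.50 on the log2 scale, or 5.64-fold, with an adjusted p of 0.00139 (limma), and kept 17.7% of its wild-type signal. The main probe was chosen by its mean over all 8 arrays, mutants included, so the share of Sox9 signal that remained is uncertain. The remaining probe (A_51_P451606), whose target spans 853 bases of genome from 112599086 to 112599938 and whose wild-type level was only -2.50 ± 0.22, read -1.85 ± 0.82 in mutants, a log2 fold change of 0.65 with an adjusted p of 0.338, and of 0.24 (adjusted p 0.227) without mutant replicate 2, so this probe did not differ detectably. The annotation of the samples does not say which exons are removed.

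**Figure D2:**
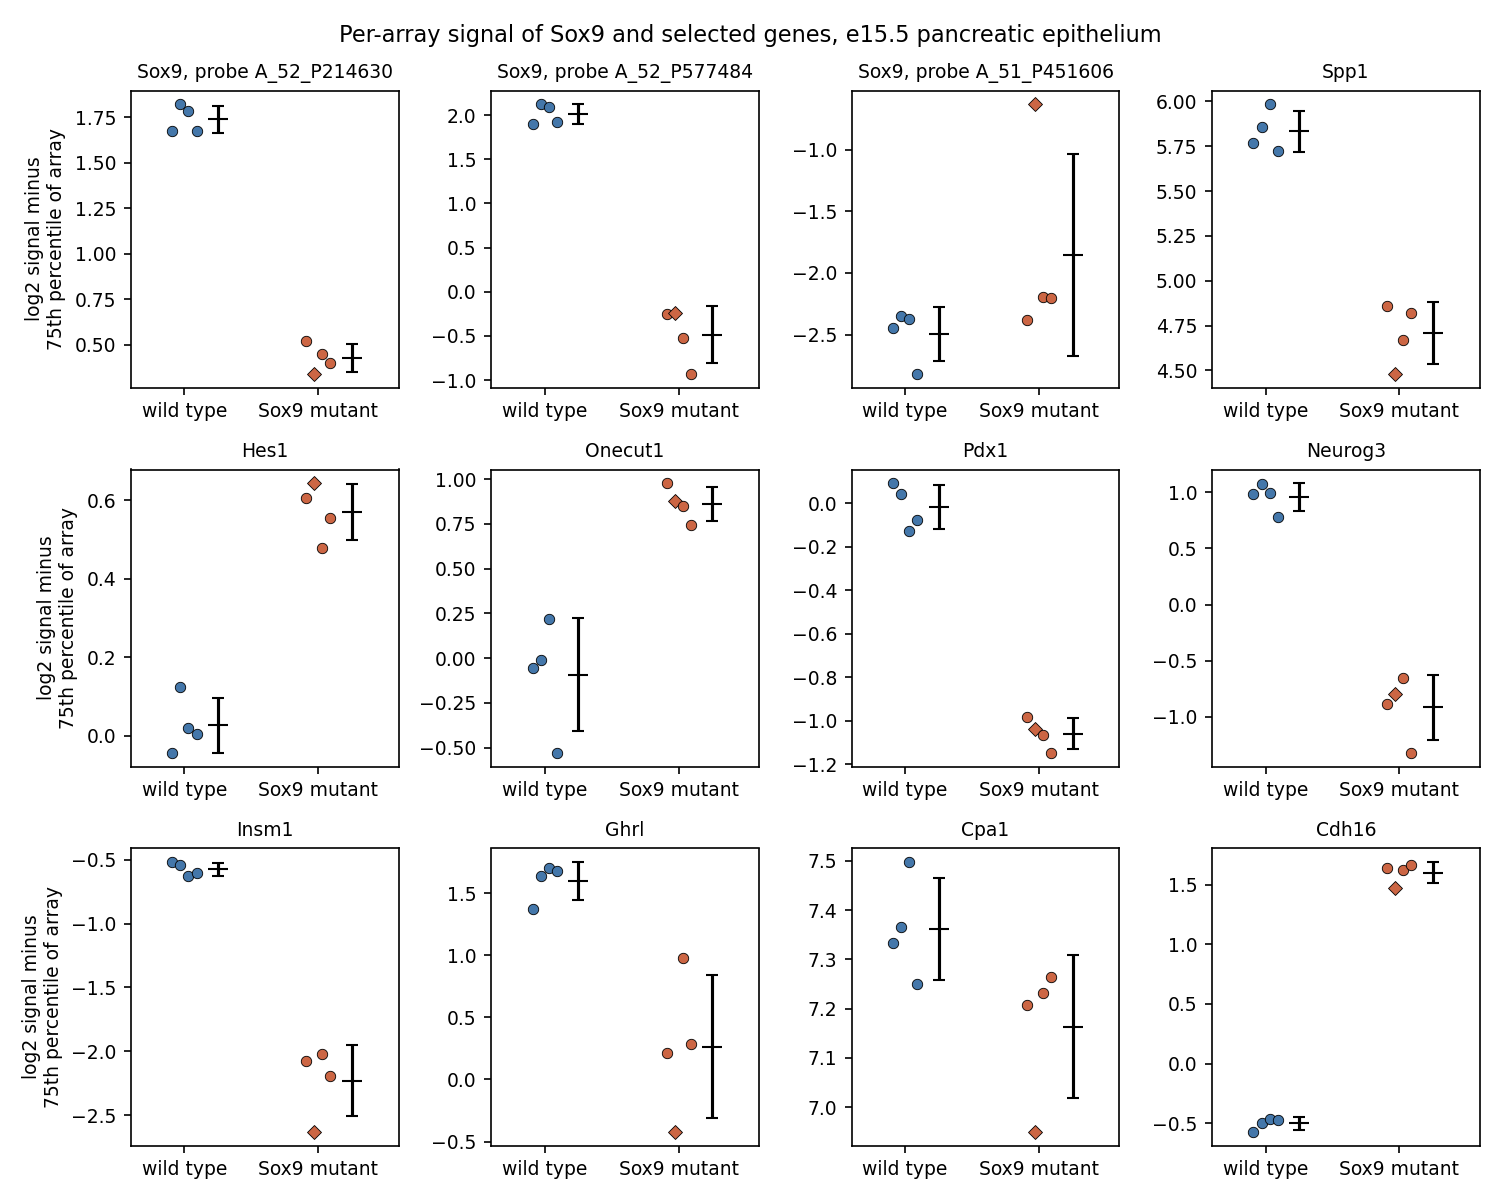
Log2 signal minus the 75th percentile of the array for the 3 Sox9 probes and 9 further genes (vertical axis; each panel has its own range), with 1 point per pool, a diamond for mutant replicate 2, and the mean ± SD of 4 pools per genotype. Signal of the main Sox9 probe was 1.74 ± 0.07 in wild type and 0.42 ± 0.08 in mutants, while Cpa1 overlapped between the genotypes.

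Of the genes named by the fixed rule, 63 were called and 25 were not. In each of the 63 the 4 mutant values all lay on one side of the 4 wild-type values. The rule itself asked for this in the genes of largest change and picked list members for being called, so neither statement is separate support. Of the 63, 25 were called in all 8 fits that left out 1 array, among them Sox9, Spp1, Hes1, Neurog3, Tox3, Insm1, Fev, Isl1, Abcc8, Pdx1, Cdh16, Fgfr4, Bbs2, Mcm3, Jun, Bapx1 (current symbol Nkx3-2), Sox10, S100b, Kctd14, Krt20, Serpina1b, Serpina1e, Serpina3a and Slc28a3. The other 38 lost their call in at least 1 such fit. The number of named genes called was 28 without wild-type replicate 1, 30 without wild-type replicate 2, 30 without wild-type replicate 3 and 37 without wild-type replicate 4. It was 32 without mutant replicate 1, 72 without mutant replicate 2, 42 without mutant replicate 3 and 40 without mutant replicate 4.

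Among the gene lists, 6 of 26 passed camera with the preset correlation, 2 towards higher and 4 towards lower expression. With a correlation estimated from the data 0 passed and 1 had an unadjusted p under 0.05, while fry called 6 lists. Fry asks whether a list moved at all and not whether it moved more than other genes, and its 6 were the endocrine progenitor, endocrine hormone and secretion, early multipotent progenitor, FGF (adjusted p 0.0274), YAP target (0.0336) and primary cilium (0.0354) lists. It did not call the neuron and Schwann cell (0.0689), immediate early (0.0689) or unfolded protein response (0.246) lists, which camera did. The exact permutation test of list means, added after the data were seen, gave 7 lists at its smallest p of 0.0286 and 0 after adjustment, at which that p became 0.106. With 4 against 4 arrays at least 15 of the 26 lists would need that smallest p for any to pass, so the 0 says little. In the following, the adjusted camera p of a list is followed by the one with the estimated correlation.

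The endocrine progenitor list had the smallest camera p of the 26. Its 20 tested members had a median log2 fold change of -0.64, 10 fell and 0 rose, with 13 and 0 adjusted over the list alone (adjusted p 1.50e-09, with estimated correlation 0.487). The mean over its members was 0.11 ± 0.08 in wild type and -0.64 ± 0.12 in mutants, with every mutant pool below every wild-type pool. Neurog3, the gene of the transient endocrine precursor, fell from 0.96 ± 0.13 to -0.92 ± 0.29, a log2 fold change of -1.88 with an SE of 0.15, or 3.67-fold (adjusted p 0.00240). Insm1 fell 3.15-fold (adjusted p 0.00255), Fev 2.19-fold (adjusted p 0.00282) and Tox3 1.89-fold (adjusted p 0.00122). The endocrine hormone and secretion list had a median of -0.71 over 36 members, of which 10 fell and 0 rose, with 19 and 0 adjusted over the list alone (adjusted p 1.97e-08, with estimated correlation 0.626). Without mutant replicate 2, 23 members of this list fell and 1 rose. Its mean was 1.07 ± 0.11 in wild type and 0.35 ± 0.34 in mutants. Isl1 (-0.87), Abcc8 (-0.85) and Pax6 (-1.26) had log2 fold changes with adjusted p of 0.00945, 0.0110 and 0.0191. Pax6 was called in 4 of the 8 fits with an array left out. The hormone genes differed in how firmly they changed. Ghrl fell 2.52-fold (adjusted p 0.0371) and was called in 2 of the 8 fits, those without mutant replicate 2 or mutant replicate 3. Ins2 had a log2 fold change of -1.44 with an adjusted p of 0.145, and of -0.88 with an adjusted p of 0.00711 without mutant replicate 2. Gcg, at 5.52 ± 0.21 in wild type and 5.75 ± 0.34 in mutants, did not differ detectably (adjusted p 0.441).

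Duct and progenitor genes changed in both directions. The duct and trunk list, which contains Sox9, had a median log2 fold change of 0.08 over 27 members. Of these 3 rose and 3 fell, with 5 and 3 adjusted over the list alone (adjusted p 0.599, with estimated correlation 0.912), and fry gave it the opposite sign to median and camera. Its mean was 0.30 ± 0.01 in wild type and 0.41 ± 0.07 in mutants (exact permutation p 0.0286, adjusted 0.106). Spp1, the osteopontin gene of the ducts, fell from 5.83 ± 0.12 to 4.71 ± 0.17, or 2.18-fold (adjusted p 0.00348), and Cldn10 fell 1.65-fold (adjusted p 0.0139), a call lost without wild-type replicate 3. Hes1 rose 1.46-fold (adjusted p 0.00690) and Onecut1 1.94-fold (adjusted p 0.0188), the latter in 4 of the 8 fits with an array left out. Krt19 had a log2 fold change of 0.36 (adjusted p 0.136) with all arrays, and of 0.48 (adjusted p 0.00613) without mutant replicate 2. Cftr had 2.34 (adjusted p 0.128), and 1.47 (adjusted p 0.00259) without mutant replicate 2. It was dim in wild type, at -5.09, though called well above background on all 4 arrays of each genotype. Bicc1 had 0.16 (adjusted p 0.381), and 0.27 (adjusted p 0.0130) without mutant replicate 2. Glis3 (0.76, and 0.12 without mutant replicate 2) and Pkhd1 (0.15, and 0.22) did not pass with all arrays or with any array left out. The early multipotent progenitor list, which also contains Sox9, had a median of -0.09 over 19 members, with 2 risen and 3 fallen, and 3 and 4 adjusted over the list alone (adjusted p 0.174, with estimated correlation 0.626). Fry called it with an adjusted p of 3.15e-04. Pdx1 fell from -0.02 ± 0.10 to -1.06 ± 0.07, or 2.06-fold (adjusted p 0.00184), and Nkx6-2 fell 1.86-fold (adjusted p 0.0160, called in 5 of the 8 fits). Nkx6-1, with a log2 fold change of -0.56, did not pass (adjusted p 0.148).

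Acinar genes showed no detectable common change with the reported settings. The acinar enzyme list had a median of 0.04 over 28 members, with 1 risen and 0 fallen, and 1 and 0 adjusted over the list alone (adjusted p 0.599, with estimated correlation 0.951). Its mean was 3.61 ± 0.24 in wild type and 3.72 ± 0.46 in mutants (exact permutation p 0.657, adjusted 0.854). In 2 of 22 alternatives the list passed towards higher expression, with normexp background correction and with array weights (lowest adjusted p 0.0167). Cpa1 was at 7.36 ± 0.10 and 7.16 ± 0.14 (adjusted p 0.231). Reg1, the called member, rose 3.96-fold (adjusted p 0.0349) but in the fits with an array left out it was called only without mutant replicate 2. The acinar transcription factor list had a median of -0.16 over 8 members, with 0 past the threshold (adjusted p 0.306, with estimated correlation 0.912). Ptf1a had a log2 fold change of -0.31 (adjusted p 0.196). Bhlhb8 (current symbol Bhlha15) had -0.48 (adjusted p 0.0972), and passed without mutant replicate 2 at -0.34. The pan-epithelial list had a median of 0.06 over 23 members, with 2 risen and 1 fallen, the same adjusted over the list alone (adjusted p 0.301, with estimated correlation 0.912, and by preset camera 0.0241 without mutant replicate 2). Cdh16, a cadherin gene, had the smallest p of all genes and rose from -0.50 ± 0.05 to 1.60 ± 0.09, or 4.30-fold (adjusted p 6.87e-05). Cldn6 rose by 0.48 and Ehf changed by -0.47 on the log2 scale.

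Of the signalling lists, YAP targets moved towards higher levels with a median of 0.19 over 13 members, 2 risen and 0 fallen, and 4 and 0 adjusted over the list alone (adjusted p 0.0394, with estimated correlation 0.664). This call was lost without mutant replicate 1 (0.0837) and without mutant replicate 4 (0.111). Ankrd1 rose 6.98-fold (adjusted p 0.0143, called in 5 of the 8 fits with an array left out) and Jub (current symbol Ajuba) 1.31-fold (adjusted p 0.0127, in 6 of the 8). Ankrd1 was dim in wild type, at -4.53, and its log2 fold change of 2.80 went as low as 1.48 among the alternatives. The Notch list had a median of -0.04 over 23 members and a mean of 0.01, of opposite sign, with 1 risen and 2 fallen, the same adjusted over the list alone (adjusted p 0.697, with estimated correlation 0.912). Beside Hes1, its called members were Dtx4 (-0.50) and Mfng (-0.32), each called only without mutant replicate 2 among the fits with an array left out. Notch2 (0.11, adjusted p 0.487) and Jag1 (-0.20, adjusted p 0.334) did not differ detectably. The FGF list had a median of -0.03 over 17 members, with 0 risen and 1 fallen, and 4 and 6 adjusted over the list alone (adjusted p 0.599, with estimated correlation 0.912). Fgfr4 fell from 1.24 ± 0.06 to 0.01 ± 0.28, or 2.34-fold (adjusted p 0.00604), while Fgfr2 at -0.28 did not pass (adjusted p 0.137). The Wnt list had a median of -0.01 and a mean of 0.05, of opposite sign, over 23 members, with 1 risen and 1 fallen, and 5 and 2 adjusted over the list alone (adjusted p 0.599, with estimated correlation 0.912). Ascl2 changed by -1.10 and Wnt4 by 0.52. The Hedgehog list had a median of 0.09 over 12 members with 0 past the threshold (adjusted p 0.564, with estimated correlation 0.912). Its smallest p belonged to Gli2, at 0.29, which passed without mutant replicate 2, and Gas1, at 0.17, which did not pass.

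The primary cilium and cystic kidney list had a median of 0.16 over 25 members, and of 0.02 without mutant replicate 2, with 2 risen and 0 fallen, the same adjusted over the list alone (adjusted p 0.0513, with estimated correlation 0.626). It passed the preset camera test without wild-type replicate 3 (0.0395), wild-type replicate 4 (0.0418) or mutant replicate 2 (0.0197). In the last of these fits 7 members had risen and 0 had fallen. Bbs2 rose by 0.59 on the log2 scale (adjusted p 0.00762) and Kif3a 1.39-fold (adjusted p 0.0203, called in 4 of the 8 fits). SOX9 cartilage targets had a median of -0.16 over 13 members, with 0 risen and 3 fallen, and 0 and 4 adjusted over the list alone (adjusted p 0.0513, with estimated correlation 0.626). Without mutant replicate 2 the median was -0.37, 0 had risen and 5 fallen, and the adjusted p by preset camera was 0.00304. Col9a3 fell 4.16-fold (adjusted p 0.0143, called in 5 of the 8 fits). Col9a2 changed by -0.41 and Col27a1 by -0.40, and the latter had 0.23 when all of its probes were averaged. Basement membrane and epithelial matrix genes had a median of -0.03 and a mean of 0.08, of opposite sign, over 20 members, with 1 risen and 2 fallen, and 4 and 2 adjusted over the list alone (adjusted p 0.902, with estimated correlation 0.951). Col4a6 changed by -0.68 and Itga6 by -0.57.

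Cell cycle genes had a median of -0.10 over 28 members, with 0 risen and 2 fallen, and 0 and 3 adjusted over the list alone (adjusted p 0.0513, with estimated correlation 0.912). The list passed the preset camera test without wild-type replicate 3 (0.0203) and without mutant replicate 1 (0.00209). It did not pass in the other fits with an array left out, and without mutant replicate 2 had an adjusted p of 0.389 and a median of -0.06. Mcm3 fell 1.64-fold (adjusted p 0.00474) and Ccnd1 changed by -0.50 (called in 3 of the 8 fits). The p53 target list had a median of 0.14 over 16 members with 0 past the threshold (adjusted p 0.323, with estimated correlation 0.912). Its smallest p belonged to Pmaip1 (0.54), which passed without mutant replicate 2, and Fas (-0.50), which did not pass. The unfolded protein response list had a median of -0.26 over 18 members, with 0 risen and 1 fallen, and 0 and 5 adjusted over the list alone (adjusted p 0.0394, with estimated correlation 0.912). This call was lost without wild-type replicate 4 (0.0619), mutant replicate 1 (0.0837) or mutant replicate 2 (0.167), without which the median was -0.15, and the exact permutation p of the list mean was 0.200. Its called member Calr changed by -0.56. Immediate early genes had a median of 0.26 over 17 members, with 4 risen and 0 fallen, the same adjusted over the list alone (adjusted p 0.00313, with estimated correlation 0.687). Jun rose 1.65-fold (adjusted p 0.00491), Atf3 2.84-fold (adjusted p 0.0366) and Ier3 1.71-fold (adjusted p 0.0291), the last 2 in 2 of the 8 fits. Fos, at 0.52 (adjusted p 0.0343), had -0.065 with normexp background correction and -0.35 with quantile normalization of all 8 arrays.

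Lists of other cell types asked whether genes of such cells changed, which does not measure how much of them the tissue held. Mean levels over members were 1.66 in wild type and 1.68 in mutants for mesenchyme, and 1.28 and 1.32 for endothelium. Pan-epithelial genes had 1.85 and 1.97, so signal of mesenchyme and endothelium genes was present in both genotypes. Such levels depend on the probes and genes chosen and give no share of cells. The neuron and Schwann cell list had a median of -0.60 over 23 members, with 0 risen and 4 fallen, and 0 and 6 adjusted over the list alone (adjusted p 6.69e-04, with estimated correlation 0.687). Its mean was -1.13 ± 0.34 in wild type and -1.66 ± 0.56 in mutants, and the exact permutation p of that difference was 0.171. S100b fell 3.07-fold (adjusted p 0.00840) and Sox10 2.05-fold (adjusted p 0.00604), while Fabp7 (-0.99) and Ngfr (-0.72) were called in 2 and 3 of the 8 fits with an array left out. Mesenchyme genes had a median of -0.005 over 26 members and a camera direction of opposite sign, with 2 risen and 0 fallen, the same adjusted over the list alone (adjusted p 0.902, with estimated correlation 0.951). Bapx1 rose by 0.58 on the log2 scale (adjusted p 0.0115), and Barx1 had 0.28 but -0.11 when arrays were centred on their median. Endothelial genes had a median of 0.03 over 20 members, with 1 risen and 0 fallen, the same adjusted over the list alone (adjusted p 0.599, with estimated correlation 0.912), the called one being Flt4 at 0.47. Erythroid genes had a median of 0.17 over 13 members, with 2 risen and 0 fallen, and 3 and 0 adjusted over the list alone (adjusted p 0.244, with estimated correlation 0.912). Without mutant replicate 2, whose list mean was -0.03 against -2.33 to -1.74 in the other mutants, the median was -0.10, of opposite sign, with 2 risen and 1 fallen. The embryonic globin genes Hbb-y (1.68) and Hba-x (1.43) had adjusted p of 0.0438 and 0.0486, and were called in 3 and 2 of the 8 fits. Myeloid and lymphoid genes had a median of 0.01 over 20 members and a camera direction of opposite sign, with 0 past the threshold (adjusted p 0.902, with estimated correlation 0.951). Their smallest p belonged to Csf1r (-0.34), which passed without mutant replicate 3, and Lyzs (current symbol Lyz2, -0.37), which did not pass. Liver, gut and spleen genes had a median of -0.004 over 17 members (-0.32 without mutant replicate 2) and a camera direction of opposite sign, with 0 past the threshold (adjusted p 0.599, with estimated correlation 0.912). Sox2 (0.43) and Ttr (0.28) had the smallest p there and passed without mutant replicate 2. The 5 Y-linked and Xist genes had a median of -0.64 with 0 past the threshold (adjusted p 0.697, with estimated correlation 0.912), and Xist (-2.11, adjusted p 0.532) and Jarid1d (current symbol Kdm5d, -0.89, adjusted p 0.627) had the smallest p.

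**Figure D3:**
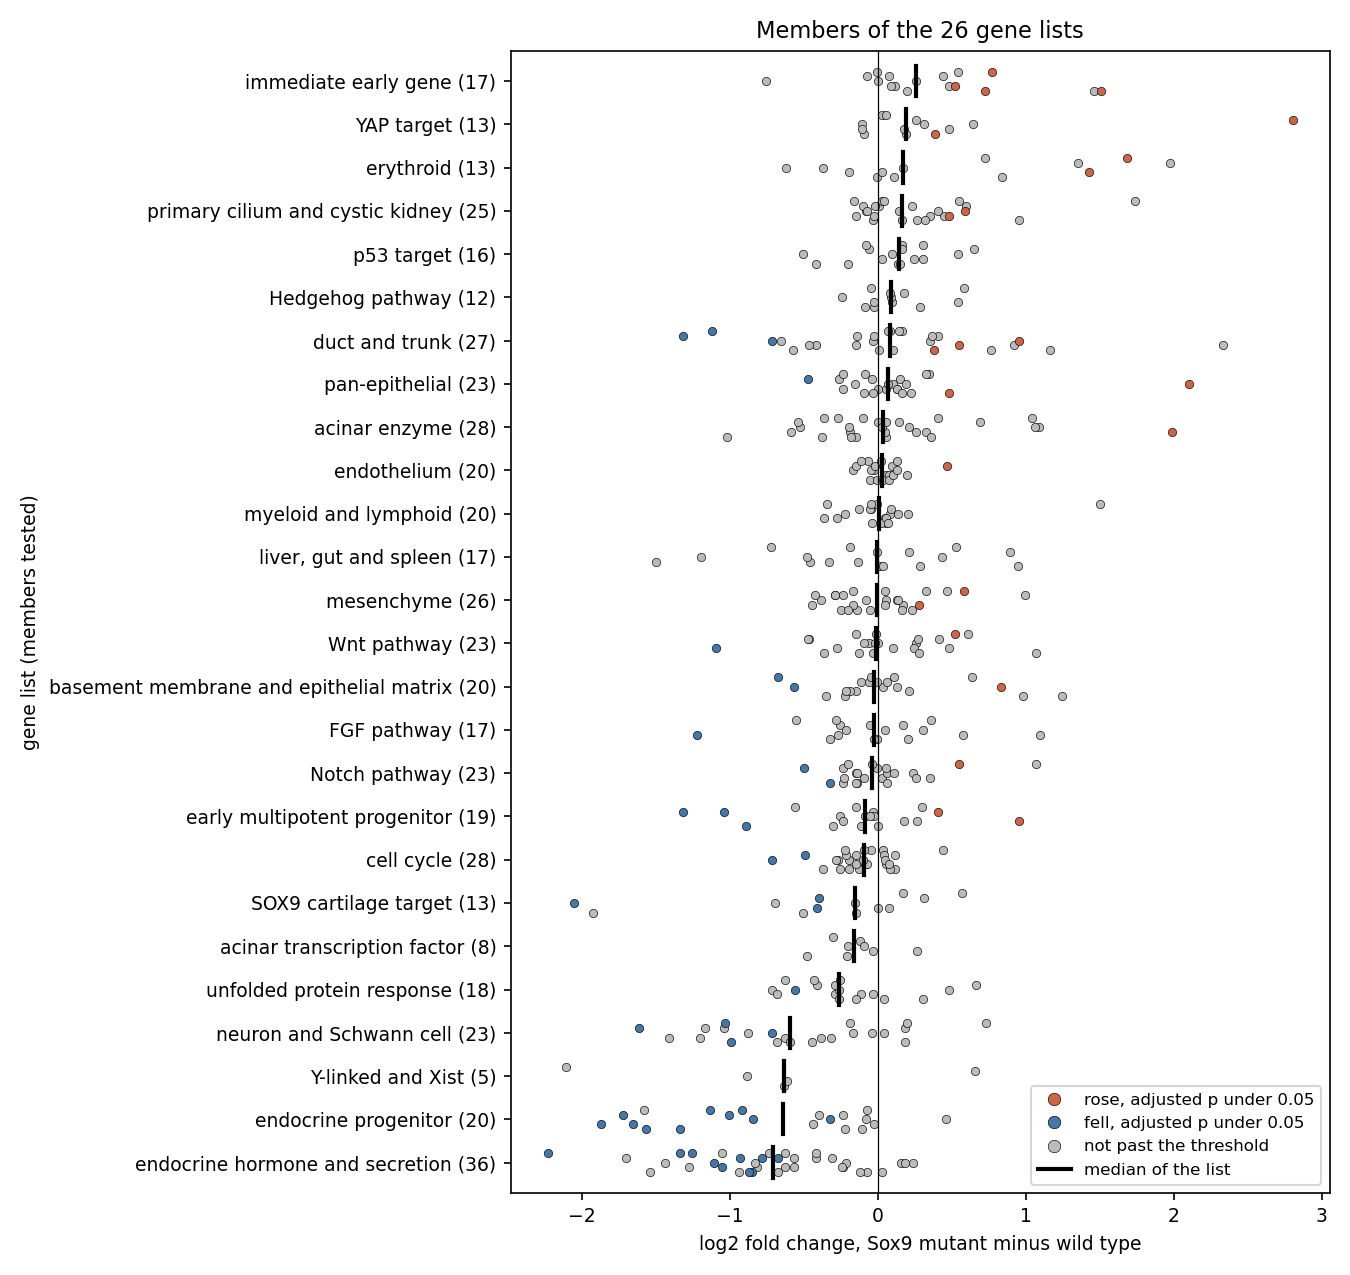
Log2 fold change, Sox9 mutant minus wild type, of the tested members of each of the 26 gene lists (1 point per gene; a black bar marks the median; orange, called higher; blue, called lower; grey, not called). The medians of the endocrine hormone and secretion list (-0.71) and the endocrine progenitor list (-0.64) lie lowest.

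The 6 genes with the largest fitted rise were Kctd14 (14.9-fold, adjusted p 0.00240), Krt20 (13.4-fold, adjusted p 0.00122), Reg3g (9.41-fold, adjusted p 0.0251), Serpina1b (8.57-fold, adjusted p 0.00312), Serpina1e (8.30-fold, adjusted p 0.00483) and the nonagouti gene, whose symbol is a. The Serpina1 paralogs are nearly identical in sequence, so which of them the probes measured is uncertain. The nonagouti probe was not well above background on any wild-type array. With the reported settings its signal was at least 3.69-fold higher in mutants, or 2.39-fold without mutant replicate 2 (adjusted p 0.0405, called in 1 of the 8 fits with an array left out). The fitted log2 fold change of nonagouti was 2.84 and went as low as 0.14 among the alternatives (adjusted p up to 0.997, limma), so its fold is uncertain. Its place among the 6 rests on a background reading, since the bound is below the rise of Ankrd1. Reg3g was called in 3 of the 8. Kctd14 and Reg3g were dim in wild type, at -5.36 and -4.77. Their log2 fold changes were 3.90 and 3.23 with the reported settings and went as low as 2.11 and 1.82 among the alternatives, so their folds are uncertain. The 6 genes with the largest fall were Serpina3a, Slc28a3, Cer1, Alox12e, Sst and Gabrp. Serpina3a was not well above background on any mutant array and was at least 7.24-fold lower with the reported settings (adjusted p 0.00240). Slc28a3, a nucleoside transporter gene, fell from 1.69 ± 0.07 to -0.89 ± 0.20, or 6.00-fold (adjusted p 2.33e-04). Cer1 (5.72-fold, adjusted p 0.0139), Alox12e (5.01-fold, adjusted p 0.0241) and Gabrp (4.64-fold, adjusted p 0.0412) were lower and were each well above background on 3 of the 4 mutant arrays. The log2 fold changes of Serpina3a, Cer1, Alox12e and Gabrp shrank to as little as -2.26, -1.31, -1.26 and -1.22 among the alternatives, so their folds are uncertain. Sst was 4.69-fold lower (adjusted p 0.0396). Of these, Cer1 was called in 6 of the 8 fits with an array left out, Alox12e and Sst in 1, and Gabrp in 2.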

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

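The tests of the array of mutant replicate 2, of a slide-wide shift and of genes shared with endocrine cells were chosen after the results were seen; the splits of the arrays and the second glial set were not.

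A value that stood apart from the other 3 of its genotype was looked for in 184 groups of 4 arrays, as the gap to the nearest of the other values divided by the whole range, above Dixon's 95% critical value. Chance gives about 1 in 20, or 9.2, and 22 were found. Of these 19 were in mutant pools, 14 of them set apart by mutant replicate 2. On that array the median processed signal (0.933), the negative control signal (0.924), the dimmest spike-in (0.908) and the median correlation with its genotype (0.989) stood apart. So did the genes Cftr (0.969), Ins2 (0.837), Glis3 (0.917), Pkhd1 (0.912), Bicc1 (0.887), Cldn10 (0.877), Pax6 (0.841), Jun (0.966), Barx1 (0.851) and S100b (0.865). Mutant replicate 3 stood apart for Gas1 (0.831), Col9a2 (0.836), Csf1r (0.918) and Sox10 (0.837), and mutant replicate 1 for Jarid1d (0.892). The 3 groups in wild type were Kif3a (0.853, replicate 1), Col27a1 (0.839, replicate 4) and Atf3 (0.922, replicate 4). Apart from the groups set apart by mutant replicate 2, no more were found than the 9.2 that chance gives.

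The first pattern is the number of called genes. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many as 1059 genes. The highest other split gave 0 (limma, adjusted p under 0.05), with 1438 genes at an unadjusted p under 0.05 against 4887 in the real split. Without mutant replicate 2, 1 of 35 splits gave as many as 3357 genes, and the highest other gave 2. Both counts were reached by the real split only. That is 1 of 35, the least this test can give, so chance is made unlikely but is not excluded. The real split is also the split by slide, so these counts cannot tell genotype from slide. For the number of gene lists chance remains open, since 20 of 35 splits gave at least the real 6 lists by camera with the preset correlation. The highest other split gave 14, which points to a structure of the samples that the preset correlation does not cover. An equal shift of all log2 signals between slides is removed when each array is scaled to its own percentile. The spike-in probes, which were added in fixed amounts and read before scaling, therefore cannot test such a shift as a cause of the calls. On 7 of 10 spike-ins, those well above background on the other 7 arrays, signal was lower on the mutant slide, without mutant replicate 2. The median difference was 0.11 log2 units (0.02 to 0.14). The median of 0.67 for the called genes was taken after scaling and from genes selected for their change, so it is no measure to set this against. Differences between slides or scans that act on single genes cannot be told apart from the effect of the genotype, because each slide held 1 genotype.

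The second pattern is the signal of dim probes on the array of mutant replicate 2. Relative to the other mutants it was raised by a median of 3.58 log2 units over 15725 probes below a level of -5, and was -0.29 for 886 probes above a level of 4. RNA of other cells in the pool as the whole cause is argued against by the dimmest 3 spike-in probes, which such RNA would leave in place and which were raised by at least 4.21 log2 units over the highest of the other arrays. These 3 were not well above background on all of the other arrays, so their rise is over a background reading, but the next 2 in brightness were, and rose by 2.96 and 2.07. Nonspecific signal on the array is a candidate explanation that the controls are consistent with: the 3 dimmest spike-ins were raised by a median of 6.26 log2 units, and the negative control median was 3.23 times the highest of the other arrays. The median local background, at 31.0 units, was within the range of the other arrays (29.5 to 31.5), so the added signal lay in the spots. What put it there was not tested. Apart from RNA of other cells, no biological explanation was tested.

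The third pattern is the lower neuron and Schwann cell genes in mutants. One candidate explanation is a smaller share of glial cells in the mutant pools, which were dissected by hand with no sort. A second set of 18 glial genes, none of them in the lists, was written before it was tested. Of its 15 tested genes all 15 were lower, 5 of them past the threshold (8 without mutant replicate 2), with a median of -0.36 (one-sided camera p 4.64e-07, with estimated correlation 0.0433) and of -0.51 without mutant replicate 2. The 2 with the brightest probes in wild type, which need not be the most abundant, were Mbp, which went from 2.67 to 2.44, and Gfra3, from 1.91 to 0.70. With all 8 arrays the median lay between the limits set in advance, -0.5 for a smaller share and -0.25 against it. Without mutant replicate 2 it just passed the limit for a smaller share (one-sided camera p 2.47e-06). The outcome thus depends on that array, which keeps this open. The other candidate is that members also expressed by endocrine cells followed the endocrine genes. All 9 such members of the list were lower, with a median of -0.60 (one-sided camera p 0.00695). The second glial set was lower too, but whether endocrine cells express its genes was not tested, so this candidate also stays open. Whether a smaller share of glial cells would also lower the 9 shared members was not tested. An effect of Sox9 deletion within glia, where the Rosa26 recombinase is active as well, stays open and untested.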

How the results depend on the processing

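Quantile normalization of 7 arrays, the lists without Sox9, the other Sox9 probes and the permutation of list means were chosen after seeing the data. No gene called with the reported settings was called in the opposite direction under an alternative, except Sdc4 (singled out after its values were seen) when probes of a gene were averaged. Over the named genes, 1278 comparisons with an alternative kept their side of the threshold, 21 of them uncalled and with the other sign, 421 lost the call, 39 gained it and in 5 a called value changed sign. Over the lists 504 kept their side, 42 of them uncalled and with the other direction of the test, 24 lost the call, 46 gained it and in 0 a called list changed its direction in the test, while the median changed sign in 69.

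Of 431 higher and 628 lower genes with 63 named genes and 6 lists called, normexp background correction left 17 higher, 63 lower, 15 named genes and 11 lists, and all of its 80 calls were among the 1059. Centring on the median left 25 higher, 31 lower and 10 named genes. With no filter there were 171, 249 and 34. Quantile normalization called 40 named genes, and its 862 genes shared 521 with the 1059. Averaging probes left 394 lower, and trend and robust options gave 1000 lower. Array weights, which gave mutant replicate 2 a weight of 0.054, called 2078 higher, 2678 lower and 11 lists, including all 1059 genes. The series table, which has no value for the main probe of 12 named genes, Sox9 and Fos among them, gave 879, 1276 and 10 lists, and quantile normalization of 7 arrays 1438, 2084 and 10 lists. The 2-fold limit left 135 and 137. Camera with an estimated correlation called 0 lists. So did the permutation of list means, where 15 lists would need its smallest p for any to pass, so that 0 says little. With the replicate number as a block, which is also the position on the slide, there were 66 higher, 50 lower and 15 named genes. Deviations of same-numbered pools correlated at only -0.02 to 0.13 across genes. With 1 array left out, higher genes ranged from 139 to 1399, lower genes from 216 to 1958, named genes from 28 to 72 and lists from 5 to 8. Fewer arrays were fitted there, and all left-out arrays but mutant replicate 2 lowered the number of genes. For the other changes the cause was not tested.

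Sox9 ranged from -1.35 to -1.29 with 1 array left out and kept its call in 18 of 19 alternatives (adjusted p 1.63e-05 to 0.0936), all but centring on the median, where it was -1.70 with an adjusted p of 0.0936. Of its other 2 probes, A_52_P577484 kept the direction and the dim A_51_P451606 had 0.65, and 0.24 without mutant replicate 2. Fos reversed to -0.065 with normexp and -0.35 with quantile normalization, Barx1 to -0.11 with centring on the median, whose shift exceeds its rise, and Col27a1 to 0.23 when probes were averaged; for the others the cause was not tested. Of 22 alternatives, without the permutation of list means, which called none of them, the endocrine progenitor and hormone lists passed in 21 each (adjusted p up to 0.626), neuron and Schwann cell genes in 20, immediate early genes in 19, YAP targets in 16 and the unfolded protein response in 11. Of lists not called with the reported settings, primary cilium genes passed in 12, SOX9 cartilage targets in 9, pan-epithelial genes in 6, cell cycle, p53 and endothelial genes in 4 each, acinar enzymes in 2, erythroid and FGF genes in 1 each, and, of 23, early multipotent genes in 2 and duct and trunk genes in 1. Dim probes were raised most on the array of mutant replicate 2, and how far this limits dim genes beside the other limits was not tested. A slide block was not run, because each slide held 1 genotype.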

Other observations

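No test in this part was chosen after its result was seen. The gene BC006965 and the positions of the Serpina genes were singled out after their values were seen.

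Genes near Sox9 could differ through strain sequence carried along with the floxed allele, which comes from a mixed FVB/N, C57Bl/6J and CD1 background, and not through loss of Sox9. Within 20 Mb of Sox9 on chromosome 11, 8 of 591 genes, or 1.35%, were called with a change of at least 2-fold, Sox9 among them, against 262 of 18659 elsewhere, or 1.40%. The odds ratio was 0.964 with a 95% interval from 0.410 to 1.94 (one-sided Fisher's exact p 0.591), so the window held no excess. A shorter linked stretch was not tested, and neither were strain differences elsewhere in the genome. Of the genes with the largest changes, Serpina1b, Serpina1e and Serpina3a lie close together on chromosome 12 (mm8 starts 104131529, 104352126 and 104522617). Serpina1b and Serpina1e were higher in mutants and Serpina3a was lower. Whether strain accounts for these changes was not tested. The unannotated transcript BC006965, whose probe lies at 112480032 to 112480091 on chromosome 11 (mm8) close to Sox9, went from -0.25 ± 0.28 to -3.93 ± 0.92, a 12.8-fold decrease (adjusted p 0.00676), larger than that of Sox9 itself.

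The pools differed in their mix of sexes. The median of 4 Y-linked genes was -5.95 in mutant replicate 1 and between -1.83 and -0.41 in the other 7 pools, and Xist was -6.74 in mutant replicate 4 and between 1.23 and 3.65 in the others.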
